A study of Mus musculus with 2 samples.

How the data were processed

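Each of the 2 samples was 1 library of dissociated corneal epithelium, made with 10x Genomics Chromium 3' v3.1 chemistry per the labels, after the epithelium had been released from the cornea with an enzyme and separated into single cells with trypsin. The control library pooled 7 left eyes and the dry eye library 6 right eyes of 7 mice. Cell Ranger 6.0.1, Seurat 4 and the mouse build mm10 are named in the submitters' processing notes, with no role or order. The deposited table held raw UMI counts per gene and cell, not normalized, for 17891 genes and 33885 cells of both libraries: 0 values were not whole and 0 were below 0, and the highest was 7968. A deposited table of cells gave the library of each cell and 1 of 13 class names per cell, 5 of them with an asterisk. How cells and genes were filtered and how cells were classed is not given in the sources used here. The lowest UMI total of a cell was 510 in control and 502 in dry eye, and the highest mitochondrial share 24.7% and 25.7%.

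Within each library, genes with counts in 1 or 2 cells were rarer (106 in control and 88 in dry eye) than genes with counts in 3 cells (484 and 517), while 764 genes were at 0 in control and 505 in dry eye. A gene seen in fewer than 3 cells of a library thus seems to have been set to 0 in many cases, so a 0 for a whole library allows counts in about 2 cells. Gene coordinates were taken from the GENCODE annotation of the same mouse build and are 1-based.

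Counts were summed per library, over all cells or per class, and divided by the library's or class's total to give CPM. The ratio of dry eye over control CPM had an exact 95% Clopper-Pearson interval from the split of the 2 counts, and shares of cells had exact Clopper-Pearson intervals. 1 count was worth 0.00522 CPM in control and 0.00483 in dry eye. Where 1 library had 0 counts, a floor of 3 counts in that library gave a ratio, and the exact limit gave a bound. A share of 0 was given with the share that 3 cells would make. UMIs remove most PCR copies, but cells of a pool are not independent replicates, so intervals and floors cover counting error only, and no p-value or standard error was computed. Genes were compared over all cells if they had at least 100 UMIs over both libraries and 20 CPM in one, and within a class if they had at least 50 UMIs and 20 CPM. A class was compared within if each library had at least 100 of its cells and if its 10 leading genes held no more markers of another type than of its own. The classes LSC*, TAC2*, Wing*, Squam* and Immune were too small in control for this. Basal, Squam, TAC1 and TAC1* passed with 0 markers of their own and 0 of another type, so for them the check of markers decided nothing. To bound free RNA, which was not removed, the upper 95% limit of a gene's mean UMIs per cell in the class with the fewest was subtracted from every class of the library with the higher level, and a difference passed if the lower limit of what was left lay above the upper limit of the other library. This bound was chosen after the data were examined.

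Genes to be named were fixed by a rule before the data were examined. Over all cells it took the 12 highest and 12 lowest ratios, ranked by the interval's bound nearest to 1, leaving out predicted genes, mitochondrial and ribosomal protein genes and haemoglobins. It took the 4 highest and 4 lowest in each class, the 2 highest and 2 lowest members of each list with at least 50 UMIs, and 10 genes whatever their values, of which 9 were in the table. A gene named by this rule in the axon guidance and neurotrophic list is not reported here. Ccl20 and Cxcl2 fall under that rule, and Tnf and the genes of the starred classes were singled out after their values were seen. For each of 25 gene lists, fixed at the same time, the median log2 ratio of members with at least 20 UMIs, its order-statistic interval over genes and its percentile among 10000 random lists matched on expression in 20 bins were computed. Another 17 lists of cell type markers were summed per library. Some list genes were not analysed here, among them Mmp9, Il6, Muc5ac, Sprr2b, Krt24 and 7 of the 8 stromal markers.

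For proliferation each cell was thinned at random to 3000 UMIs, which left out 1094 control and 784 dry eye cells that were shallower. No doublet caller was run, and the 5% of each library's cells with the most UMIs were left out as an alternative. An own clustering used 2000 variable genes, 30 components, 15 neighbours and Leiden resolution 1, and gave 18 clusters. For 79.1% of cells, the class most common in their cluster was their own.

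The interval and list calculations were tested on simulated counts of the whole-suspension comparison with known ratios. Counts were drawn independently, as the intervals assume. The test thus checks the calculation and not whether the intervals hold where a few cells carry many counts. For 12895 unchanged genes the 95% interval held the true ratio in 95.7%. With true ratios of 2, 0.5, 4 and 0.25, it did so in 94, 95.7, 96 and 93.8% of 50, 47, 50 and 48 genes. A simulated list of 50 genes raised 2-fold had a median log2 ratio of 1.00, and an unchanged list of 50 genes 0.00.

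Alternatives fixed before the data were examined were TMM factors from edgeR, size factors from DESeq2, totals without the 50 genes with the highest counts, a mean over cells, no gene minimum, only cells with at least 2000 UMIs or under 10% mitochondrial UMIs, the dry eye classes weighted to the control library's class shares, and other definitions of proliferating cells, leukocytes and classes. Alternatives chosen after seeing the data were leaving out the starred classes, counting starred cells with their unstarred class, leaving out genes at 0 in 1 library, and leaving out the 10 cells of each library with the most counts of a gene. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and leidenalg 0.10.2, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.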

Results

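The data were single-cell transcriptomes of dissociated corneal epithelium. The donors were 7 male mice of the strain C57BL/6J, aged 10 weeks, whose right extraorbital and intraorbital lacrimal glands had been removed to dry the right eye. Corneas were collected on day 9. Epithelium of the 7 untreated left eyes was pooled into 1 control library, and epithelium of 6 right eyes into 1 dry eye library, with 1 injured eye left out. Both pools came from the same animals, and the side of the eye went with the treatment. The control library held 17465 cells and 191493194 unique molecular identifiers (UMIs), with a median of 8248 UMIs and 2146 genes per cell. The dry eye library held 16420 cells and 207030777 UMIs, with medians of 9086.5 UMIs and 2207 genes. Mitochondrial UMIs had a median of 1.76% of a cell's total in control and 1.74% in dry eye. Xist, which cells of male mice should lack, had 8 and 7 UMIs in the 2 libraries. With 1 library per group no test between groups was possible and no difference has a replicate check, so each value is given for both libraries with an exact 95% interval that covers counting error only. All differences below compare these 2 libraries.

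The first comparison asked how the makeup of the epithelium differed in dry eye, with the 13 classes of the authors' annotation under the names given there. LSC cells and cells of the TAC classes took larger shares of the dry eye library, and Basal and Wing cells smaller ones. The LSC class, with Gpha2 and Cd63 among its 10 leading genes, made up 1.53% of control cells (1.35 to 1.72) and 3.61% of dry eye cells (3.33 to 3.90). TAC1, led by genes of DNA replication, took 5.85% (5.51 to 6.21) of control and 6.92% (6.53 to 7.32) of dry eye cells, and TAC2, led by genes of mitosis, 8.49% (8.08 to 8.91) and 11% (10.5 to 11.5). Basal cells made up 24.2% (23.6 to 24.9) of control and 17.4% (16.8 to 18.0) of dry eye cells. The share of Wing cells was 32.4% (31.7 to 33.1) in control and 20.6% (20 to 21.3) in dry eye. Conj cells took 8.96% (8.54 to 9.39) and 11.2% (10.7 to 11.7), and Squam cells, at 17.5% (16.9 to 18.1) and 18.1% (17.5 to 18.7), had intervals that overlapped.

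Asterisks marked 5 further classes, LSC*, TAC1*, TAC2*, Wing* and Squam*, and 91.2% of their cells came from the dry eye library. Together they held 172 control cells, 0.985% (0.844 to 1.14), and 1793 dry eye cells, 10.9% (10.4 to 11.4). TAC1* took 0.762% of control and 2.88% of dry eye cells, TAC2* 0.120% and 3.48%, Wing* 0.0687% and 2.72%, and LSC* 0.0344% and 0.518%. Squam* had 217 dry eye cells, 1.32% (1.15 to 1.51), and 0 of 17465 control cells, where 3 cells would make 0.0172% and the exact upper limit was 0.0211%. The meaning of the asterisk is not stated, and a class drawn almost wholly from 1 library may reflect that library and not a cell type. Wing and Wing* together made up 32.4% and 23.4%, LSC and LSC* 1.56% and 4.12%, and TAC2 and TAC2* 8.61% and 14.5%. In the dry eye library LSC* had 0.00801 times the Gpha2 level of LSC (0.00584 to 0.0107) and 0.0319 times that of Krt15, so the sum with LSC joins unlike cells.

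**Figure D1:**
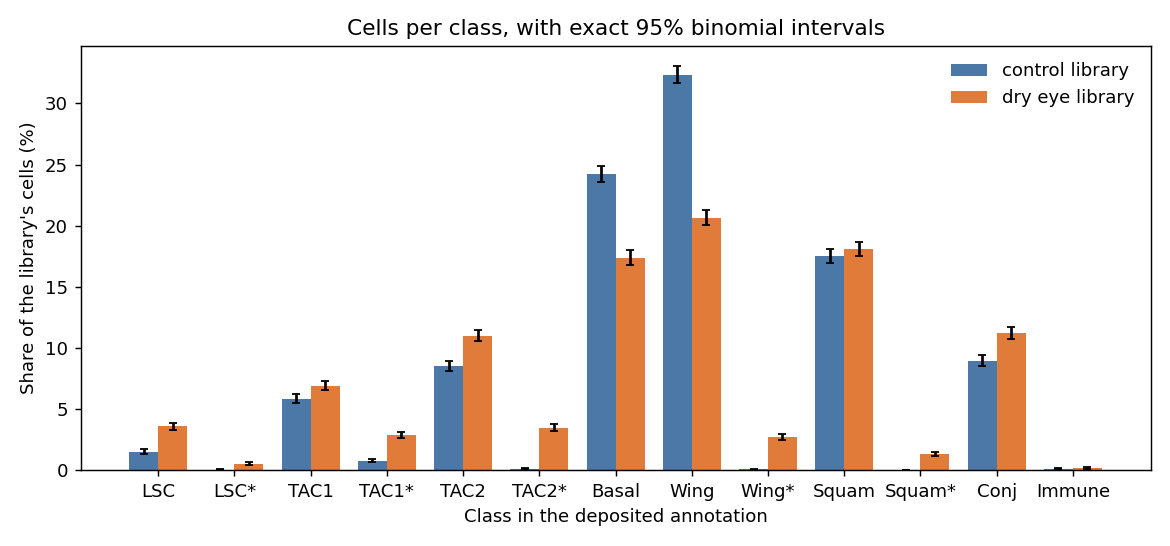
Share of each library's cells (vertical axis, percent) in each of the 13 classes of the deposited annotation (horizontal axis), for the control and the dry eye library; error bars are exact 95% binomial intervals. Wing cells made up 32.4% of control and 20.6% of dry eye cells, and LSC cells made up 1.53% and 3.61%.

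The second comparison asked whether more cells were dividing. Cells of TAC1, TAC2, TAC1* and TAC2* together made up 15.2% (14.7 to 15.8) of the control library and 24.3% (23.6 to 25) of the dry eye library. TAC1 and TAC2 alone made up 14.3% (13.8 to 14.9) and 17.9% (17.4 to 18.5), so starred cells held most of that difference. Among LSC, TAC and Basal cells alone all 4 classes made up 37.1% (36.0 to 38.3) and 53% (51.9 to 54.2). After each cell was thinned to 3000 UMIs, 1230 of 16371 control cells, 7.51% (7.11 to 7.93), and 1723 of 15636 dry eye cells, 11% (10.5 to 11.5), had a UMI of Mki67 or Top2a, 2 genes of dividing cells. Squam and Squam* cells, taken as a layer that should not divide, gave a background of 0.502% (0.281 to 0.827) in control and 1.47% (1.07 to 1.96) in dry eye after the same thinning. Without thinning the shares were 11.7% and 18.4% of all cells, against 1.64% and 3.79% of Squam and Squam* cells at median depths of 9342.5 and 9639 UMIs. Within TAC2 the thinned shares were 63.5% (60.8 to 66.0) and 64.0% (61.7 to 66.3), and within Basal 2.15% (1.70 to 2.66) and 2.43% (1.88 to 3.09). In dry eye they were 16.6% (13.3 to 20.3) within TAC1* and 22.0% (18.6 to 25.7) within TAC2*. Within all TAC cells together they were 41.0% (39 to 42.9) and 37.8% (36.3 to 39.4), and with the starred classes left out they were 7.52% and 10.8% of the other cells.

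Summed over all cells, the genes with the highest ratios of dry eye over control included keratins, cornified envelope precursors and alarmins. Krt16, a keratin of stressed and wounded epidermis at chromosome 11, 100246091 to 100248902, had 34.3 CPM (counts scaled to equal library totals) in control and 1150 in dry eye, a ratio of 33.5 (32.7 to 34.3). Krt14, the keratin of basal layers of stratified epithelia at chromosome 11, 100203162 to 100207548, was 10.6-fold higher (10.5 to 10.7), from 183 to 1940 CPM. Sprr1b, a precursor of the cornified envelope at chromosome 3, 92436809 to 92438789, had 0 control UMIs and 21329 dry eye UMIs in 1067 cells. It was 6576-fold higher against a floor of 3 counts in the library, and at least 5348-fold by the exact limit. That bound assumes that the control 0 was measured: zeros of whole libraries in the table could hide a gene seen in about 2 cells. Sprr1a, another cornified envelope precursor, was 32.4-fold higher (31.3 to 33.6). Cnfn and Cdsn, which encode proteins of the cornified envelope and of the junctions of cornified cells, were 18.9-fold (18.1 to 19.8) and 16.7-fold (15.1 to 18.4) higher, and Dmkn, a secreted protein of epidermis, 49.7-fold (43.5 to 57.1). The alarmins S100a8 and S100a9 were 36.4-fold (32.5 to 40.8) and 26.3-fold (24.9 to 27.8) higher, with 44.7% of the dry eye counts of S100a8 in 10 cells. Most of these dry eye counts lay in starred cells: LSC* held 5519 and Wing* 5677 of 12421 UMIs of S100a8, and 11633 and 21213 of 37449 of S100a9. Within Wing cells S100a8 was 9.09-fold and S100a9 16.3-fold higher, but S100a8 had a ratio of 0.268 (0.182 to 0.392) in LSC cells and S100a9 of 0.599 (0.541 to 0.662) in Squam cells. With starred cells counted in, these became 17.0 (13.8 to 21.3) and 1.17 (1.08 to 1.27). Ly6d, Akr1b8, an aldo-keto reductase, and Fabp5, an epidermal fatty acid-binding protein, were 10.7-fold (9.83 to 11.6), 7.99-fold (7.35 to 8.70) and 6.92-fold (6.87 to 6.97) higher. Without the starred cells all 12 stayed higher, most of them by less: Sprr1b by at least 1512-fold, Sprr1a 20.3-fold, Cdsn 17.1-fold, Cnfn 11.3-fold, Krt16 7.0-fold, Dmkn 5.11-fold and Krt14 5.0-fold. The ratios were then 3.70 for Fabp5, 3.55 for Akr1b8, 3.27 for Ly6d, 3.19 (2.80 to 3.66) for S100a8 and 2.25 (2.10 to 2.41) for S100a9.

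Far fewer genes were lower. Of 4775 genes with enough counts, 54 had a ratio of at least 2 and 6 a ratio of at most its inverse, and the median log2 ratio of all of them was -0.05. Fxyd4, a regulator of the sodium pump at chromosome 6, 117933559 to 117937692, went from 52.0 to 20.3 CPM, a ratio of 0.390 (0.376 to 0.404). Ttc36 had a ratio of 0.428 (0.418 to 0.437), Sdccag8, a centrosome gene, 0.429 (0.406 to 0.454), and Cyp26b1, which degrades retinoic acid, 0.454 (0.436 to 0.472). The ratio was 0.471 (0.448 to 0.496) for the scaffold gene Dlg2 and 0.494 (0.469 to 0.520) for Necab1, a calcium-binding protein. Ces1d, Pdhx, Osbpl6, Mpped2, Dmrta2os and Kctd12 followed, with ratios of 0.516 to 0.545. With the dry eye classes weighted to the control library's shares, the counts of genes past 2-fold were 29 higher and 1 lower. Leaving out the starred classes gave 33 and 3.

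Several genes were followed whatever their values. Gpha2, a marker of the limbal stem cell zone, was 2.40-fold higher (2.35 to 2.45), and Sparc, a matricellular protein, 4.09-fold higher (3.89 to 4.29). Krt6a was 1.52-fold higher (1.51 to 1.52). Top2a was 1.48-fold (1.43 to 1.52) and Mki67 1.29-fold (1.24 to 1.33) higher, but at the control library's class shares Mki67 had a ratio of 0.957. Pax6, the master regulator of the eye field, had a ratio of 0.835 (0.827 to 0.844). Krt12, the keratin that marks corneal differentiation, had a ratio of 0.892 (0.891 to 0.894), which became 1.05 at the control class shares. Krt15 had a ratio of 0.946 (0.943 to 0.949), which became 1.01 as a mean over cells and 1.03 without starred classes. Mmp9 was not analysed here.

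Of the 25 gene lists fixed before the data were examined, 11 had a median above and 2 below the middle 95% of random lists of equal size and expression, and 12 lay within it. The cornified envelope list stood highest, with a median log2 ratio of 2.81 (0.56 to 4.79, the interval over genes), above all 10000 random lists: 15 of its 21 measured members were at least 1.5-fold higher and 0 were lower by as much. Its extremes were Sprr1b and Sprr2d, against Krt1 at 0.80 (0.737 to 0.869) and Evpl at 0.856 (0.848 to 0.864). Sprr2d had 0 and 990 UMIs, 305-fold higher against the floor and at least 248-fold by the exact limit. Of its dry eye UMIs 837 lay in Wing* cells, and 58.4% in 10 cells. Sprr2d is so close in sequence to its neighbours that its reads may be shared. Of 4 stress keratins 3 were at least 1.5-fold higher (median 1.40), with Krt17 at 4.57 (4.42 to 4.74) and Krt6b at 1.28 (1.28 to 1.29). Of the epithelial matrix and wound list 12 of 21 members were higher and 1 lower (median 1.01, 0.41 to 3.03), with the collagenase Mmp13 at 33.5 (19.8 to 61.7) and its inhibitor Timp1 at 26.6 (18.2 to 40.7) but Fn1, fibronectin, at 0.807 (0.785 to 0.830) and Postn at 0.488 (0.300 to 0.778). Of 13 axon guidance and neurotrophic genes 7 were higher, among them Sema3c at 10.0-fold (7.45 to 13.8), while Sema3b stood at 0.694 and Efnb2 at 0.781. That list's median of 1.08 had an interval over genes of -0.33 to 1.52 and was 0.05 when only genes with at least 100 UMIs were kept. Without starred cells Sprr2d had 24 dry eye UMIs and was at least 6.44-fold higher by the exact limit. The ratios were then 5.88 for Mmp13, 6.46 for Timp1 and 3.05 for Sema3c.

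Cell cycle genes were moderately higher as a group. All 20 S phase genes were measured and 15 were at least 1.5-fold higher (median 0.67, 0.60 to 0.86), from Hells at 2.35 (2.22 to 2.49) and Uhrf1 at 2.08 (1.95 to 2.21) down to Slbp at 1.27 (1.23 to 1.31) and Pcna at 1.12 (1.09 to 1.15). Of 24 G2 and M phase genes 10 were higher (median 0.56, 0.45 to 0.62), with Tacc3 at 1.64 (1.54 to 1.74) and Ccna2 at 1.62 (1.53 to 1.71) and with Kif11 at 1.24 (1.16 to 1.33) and Cenpf at 1.14 (1.10 to 1.17). At the control library's class shares the S phase median was 0.21 and the G2 and M median 0.09, and Pcna, Cenpf and Kif11 turned below 1, to 0.941, 0.885 and 0.887. Within TAC2 cells the 2 medians were 0.10 and -0.05.

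Glycolysis genes were higher in 6 of 15 cases by 1.5-fold (median 0.50, 0.32 to 0.88), led by the lactate exporter Slc16a3, at 46.5-fold on 7 and 352 UMIs, and by Pfkp at 6.07 (5.19 to 7.13); Gpi1 was at 1.21 and Aldoa at 1.14. Limbal and progenitor genes had 6 of 12 higher (median 0.46, -0.18 to 1.31), with Ifitm3 at 6.05 (5.90 to 6.21) beside Krt14, and with Abcg2 at 0.771 and Lrig1 at 0.727. For genes of TGF-beta and BMP signalling, 6 of 15 were higher (median 0.49, 0.10 to 0.67), including Tgfbr2 at 1.78 and Bambi at 1.76. NF-kB response genes (median 0.39, -0.12 to 0.79, 4 of 13 higher, 2 lower) included Bcl3 at 3.56 (3.32 to 3.82) and Icam1 at 1.97, which became 0.655 at the control class shares. Of the 111 control UMIs of Icam1, 82.0% lay in 10 cells. Cytokines, chemokines and alarmins went both ways (median 0.28, -0.19 to 1.13, 8 of 19 higher and 4 lower). The chemokines Cxcl2 and Ccl20 were lower in dry eye, Cxcl2 at 0.0654 (0.0528 to 0.0802) on 1400 and 99 UMIs and Ccl20 on 108 and 0 UMIs, but 10 cells held 96.6% of the control counts of Cxcl2, and 6 cells all those of Ccl20. Cxcl1, at 0.241, turned to 1.85 without the 10 cells of each library with the most of its counts. Without starred cells the ratios were 16.7 for Slc16a3, 3.51 for Pfkp, 3.28 for Ifitm3, 4.99 for Icam1 and 0.00761 for Cxcl2.

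Type I interferon genes were the list that stood lowest. Of 17 measured members 6 were at least 1.5-fold lower and 1 higher (median -0.30, -0.70 to -0.09), at percentile 0.03 of random lists. Rsad2 had a ratio of 0.318 (0.221 to 0.449), with 67.9% of its control counts in 10 cells, and Usp18 of 0.453 (0.395 to 0.518), while Ifit2 stood at 1.87 (1.51 to 2.33) and Ifi27l2a at 1.01 (0.948 to 1.07). Within LSC cells 6 of 10 members were lower and 0 higher (median -0.80), and within Squam cells 7 of 16 were lower and 0 higher (median -0.53), while TAC1 cells had a median of 0.14. Corneal identity genes had a median of -0.17 (-0.26 to 0.17) at percentile 0.6, with 0 of 12 higher and 1 lower by 1.5-fold: Dsg1a, a desmoglein, at 0.615 (0.608 to 0.623). Gsta4 was at 0.769, Clu at 1.42 and Klf4 at 1.15. The interferon gamma list had a median of -0.10. MHC class II had a median of -0.06, which became 0.44 in cells with at least 2000 UMIs and -0.73 at the control class shares. Of this list H2-Aa, H2-Ab1, H2-Eb1 and Cd74 had 7691 to 18882 CPM in Immune cells and at most 3.57 in any other class. The 20 control and 31 dry eye Immune cells had medians of 1351 and 918 UMIs. These genes thus say little about epithelial cells.

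**Figure D2:**
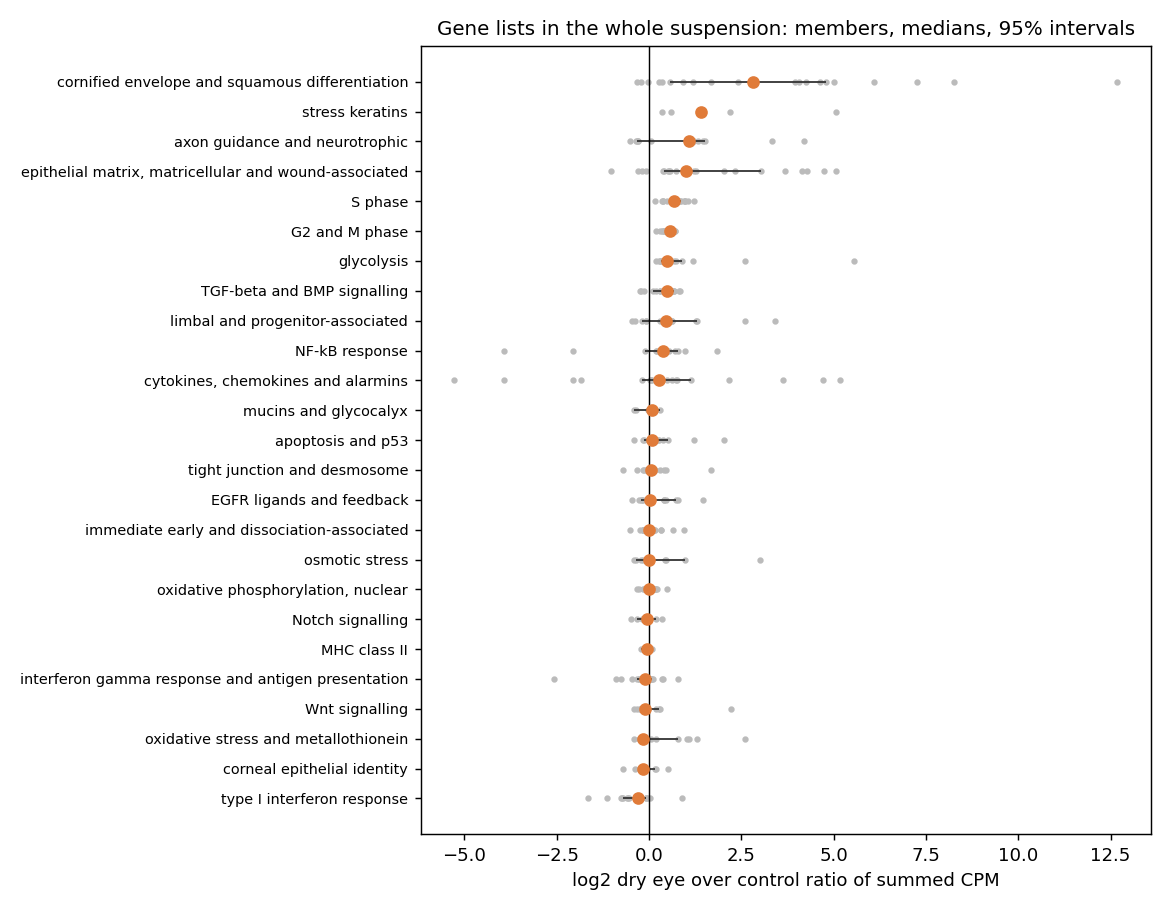
Dry eye over control log2 ratio of summed CPM (horizontal axis) for the measured members of the 25 fixed gene lists (vertical axis): grey points are genes, orange points list medians and bars the exact 95% interval of the median over genes, where a list is long enough to have one. The cornified envelope list has the highest median, 2.81, and type I interferon response the lowest, -0.30.

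Genes were then compared within the 8 classes that had at least 100 cells in each library, apart from the class mix. Krt16, Krt14, Fabp5, Sparc, Akr1b8, Cstdc5, Krt6a and Sprr1a were higher in dry eye in all 8 classes by their counting intervals. Free RNA adds UMIs to cells that do not express a gene, and was bounded for each gene by its UMIs per cell in the class with the fewest, which itself cannot pass. Beyond that bound Krt14, Fabp5 and Cstdc5 were higher in 7 of the 8 classes, Krt16, Krt6a and Sparc in 6, Sprr1a in 5 and Akr1b8 in 4. Krt16 had a ratio of 344 (181 to 753) in TAC2, on 9 and 4460 UMIs, 25.2 (23.7 to 26.8) in Wing and 7.01 (4.94 to 10.3) in LSC cells; in Basal and TAC1 cells Krt16 and Sprr1a were within the bound. Krt14 was 20.7-fold higher in Wing, 10.1-fold (9.54 to 10.8) in Conj, 2.69-fold in Basal and 1.53-fold in LSC cells. Sprr1b was at 0 control UMIs in Wing and Squam cells and, against a floor of 3 counts, 1821-fold and 245-fold higher there. Wing cells also had 58.7-fold more Cnfn (47.2 to 73.9), and Squam cells 15.1-fold more Cdsn (13.5 to 16.9). Npy, neuropeptide Y, was 4.08-fold (3.43 to 4.89) higher in Basal and 6.69-fold (4.48 to 10.4) in TAC1 cells, and the immediate early gene Fosb 3.21-fold and 4.32-fold. Fosb had a ratio of 0.552 (0.437 to 0.695) in Conj cells, but this value did not pass the bound for free RNA. Conj cells had 4.31-fold more Lgals7, 3.96-fold more Apoe and 3.19-fold more Gpha2. LSC cells had 4.77-fold more Clu (4.17 to 5.49) and 3.48-fold more Ly6a (2.91 to 4.19), while their Gpha2 ratio was 1.13, or 0.851 with LSC* cells counted in, which had 45 dry eye UMIs of Gpha2 beside 14833 in LSC cells. Ly6a had a ratio of 0.719 in Squam and Apoe of 0.922 in LSC cells.

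Fxyd4, Ttc36, Cyp26b1, Ces1d, Dlg2, Mpped2, Pdhx and Pax6 were lower in all 8 classes by their counting intervals, Pax6 by little (0.743 to 0.960) and with a ratio in Squam cells that turned to 1.10 under TMM factors. Beyond the bound for free RNA Fxyd4 was lower in 7 classes, Ttc36 and Cyp26b1 in 4, Ces1d in 3, Dlg2 and Mpped2 in 2, Pdhx in 1 and Pax6 in 0. Fxyd4 was at 0.277 (0.228 to 0.334) in TAC1 and 0.353 (0.288 to 0.431) in TAC2 cells. Plac8 was lower in Basal, 0.462 (0.429 to 0.498), LSC, 0.292 (0.221 to 0.386), TAC1, 0.435, and TAC2 cells, 0.428. Among the lowest genes of single classes were Cyp4a12a at 0.206 (0.182 to 0.233) in Wing, Cyp4a12b at 0.414 (0.366 to 0.467) in Basal, Cyp2b19 at 0.376 in TAC1 and Cyp2a5 at 0.357 in Squam cells. Squam cells also had less F3, tissue factor, at 0.293 (0.262 to 0.327), and Ccn1 at 0.311 (0.284 to 0.339). In LSC cells the lowest were Ifit3 at 0.206 (0.119 to 0.349), Pygl at 0.220 and Gbp2 at 0.245, on 41, 48 and 59 control UMIs. Krt12 was 1.41-fold higher in Squam cells, but lower in LSC, 0.521, and TAC1* cells, 0.528. The values of Plac8, of Cyp4a12b, of F3 and of Krt12 in LSC cells did not pass the bound for free RNA. Of the 8 classes the cornified envelope list had its highest median, 3.16 (0.26 to 4.59), in Wing cells.

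**Figure D3:**
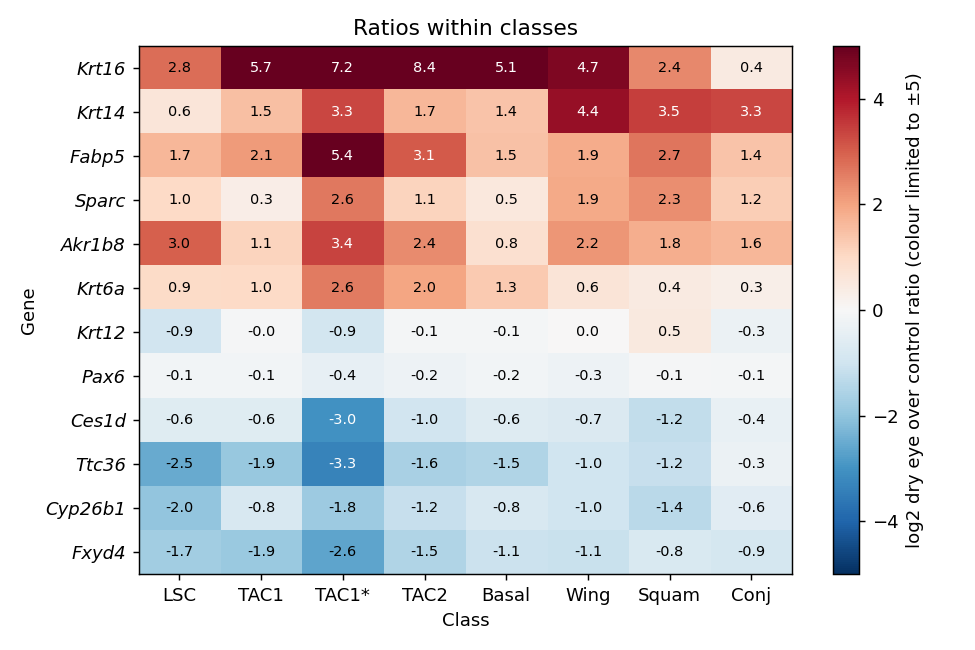
Dry eye over control log2 ratio of summed CPM for 12 genes (vertical axis) in the 8 classes compared (horizontal axis); each cell gives the value to 1 decimal, and colour is limited to a log2 ratio of 5 in either direction. Krt16, Krt14, Fabp5, Sparc, Akr1b8 and Krt6a are above 0 in all 8 classes, and Pax6, Ces1d, Ttc36, Cyp26b1 and Fxyd4 below 0, except that Pax6 in Squam cells turns to a ratio of 1.10 under TMM factors. Free RNA was not subtracted.

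In some classes the cells of the 2 libraries did not lie together. In an own clustering of all cells, 91.0% of control TAC1* cells were in cluster 5, with the unstarred TAC1 cells, and 96.4% of dry eye TAC1* cells in cluster 11, which held 0 control cells, so the TAC1* ratios compare cells of unlike clusters. Of Squam cells, 40.4% of control were in cluster 2 and 49.1% of dry eye in cluster 8, and of Wing cells 40.0% of control in cluster 1 and 33.4% of dry eye in cluster 9. Cluster 16 held 48.7% of control and 67.4% of dry eye LSC cells, and cluster 6, mostly Conj cells, 26.2% and 17.9%. Another 15.7% of control LSC cells were in cluster 1, mostly Wing cells. Cluster 5, mostly TAC1 cells, held 16.2% of dry eye Basal cells. Ratios within these classes thus also compare unlike mixes of clusters. TMM factors shifted all ratios upward by a median log2 of 0.19 in Squam, 0.12 in Wing and 0.11 in LSC cells, so ratios close to 1 in these classes depend on the scaling. In Squam cells 40 genes were at least 2-fold higher and 25 lower, against 66 and 8 under TMM factors. In LSC cells the counts were 26 and 55, against 36 and 30. Under other scalings they differed again: as a mean over cells they were 55 and 170 in LSC cells and 36 and 23 in Squam cells, and without the 50 genes with the highest counts 53 and 80, and 71 and 36.

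The Immune class was small in both suspensions. It held 20 control cells, 0.115% (0.0700 to 0.177), and 31 dry eye cells, 0.189% (0.128 to 0.268), with overlapping intervals. The summed markers of all leukocytes had 2.76 CPM in control (2.53 to 3.01) and 2.77 in dry eye (2.55 to 3.01), and those of macrophages and dendritic cells 23.2 and 22.6. The neutrophil list had 13 and 246 CPM, and of its 50984 dry eye UMIs 12421 were S100a8 and 37449 S100a9, which keratinocytes also express. Conjunctival markers, which include Krt17, had 3131 and 4746 CPM, beside the Conj class at 8.96% and 11.2% of cells, and keratinizing markers 51.8 and 122. The conjunctival sum is no measure of conjunctival cells alone. Its Krt13 had 5985 CPM in Squam and 6113 in Conj cells, and its Krt19 1575 CPM in Squam* and 2284 in Conj cells. T or NK cell markers had 0.924 and 1.47 CPM, endothelial ones 2.64 and 3.92, melanocyte ones 2.65 and 2.48, nerve-associated ones 1.87 and 1.94, goblet cell ones 12.6 and 11.8, and erythrocyte ones 2.47 and 1.76. The T or NK and endothelial sums hold counts of epithelial classes. Trac had 1.82 CPM in Basal and 0 in Immune cells, and in Basal cells Slc4a11 had 4.84 CPM against 0.214 for Pecam1. Their rises thus do not show more T cells or endothelium. Of the stromal list only Dcn was used, with 20 and 62 UMIs.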

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

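No paired analysis was possible because each group has 1 pooled library. Of 341 alternative values of counts, shares and list medians 289 stayed within the limits set for them and 52 did not. Of the values of single genes 1309 stayed within their counting intervals. Another 17, whose intervals did not hold 1, turned to the other side of 1, and 652 left their intervals in other ways. Values whose interval held 1 could cross it without being counted among the 17. In each case below the cause was not tested unless it is given. The libraries are deep enough that counting error is small for most named genes, and the lack of replicate libraries limits every comparison. Alternatives that leave out starred classes, merge them, do not count them as cycling or leave out the 10 cells with the most counts were chosen after seeing the data.

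With the dry eye classes at the control library's shares, 29 genes over all cells were at least 2-fold higher and 1 lower, against 54 and 6. The medians of the S phase list, 0.67, G2 and M list, 0.56, and MHC class II list, -0.06, became 0.21, 0.086 and -0.73. The ratio of Krt12 turned to 1.05, Mki67 to 0.957, Pcna to 0.941, Cenpf to 0.885, Kif11 to 0.887, Icam1 to 0.655 and Axin2, 1.23 before, to 0.980. By construction this alternative removes differences in the class mix. MHC class II had a median of 0.44 in cells with at least 2000 UMIs.

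Under TMM factors the count of genes at least 2-fold higher in Squam was 66, not 40, and of genes lower 8, not 25. Lower genes numbered 30, not 55, in LSC and 1, not 4, in Wing. Ratios turned to 1.06 for Krt15 in Wing, 1.10 for Pax6 in Squam and 1.004 for Top2a in TAC2. As a mean over cells, 55 genes were higher and 170 lower in LSC, against 26 and 55, 1 was lower in Conj, against 0, and 3, not 6, over all cells; Krt15 turned to 1.01 over all cells and 1.05 in Wing. Totals without the 50 genes with the highest counts gave 53 higher genes in LSC and 71 in Squam, and 7 lower ones in TAC2, not 4, and 10 over all cells. Without a minimum of counts, 1024 genes were higher and 549 lower over all cells, because genes with few counts then enter. Without the 5% of cells with the most UMIs, Krt15 in Wing turned to 1.02.

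Without starred classes 33 genes were higher and 3 lower over all cells, Krt15 turned to 1.03, and the medians of S phase, 0.67 before, and of glycolysis, 0.50 before, became 0.50 and 0.32. With starred cells counted in their unstarred class, higher and lower genes numbered 160 and 112 in LSC, 53 and 17 in TAC1, 68 and 23 in TAC2 and 83 and 13 in Wing, against 26 and 55, 15 and 4, 26 and 4, and 48 and 4. Gpha2 in LSC turned to 0.851, with 45 dry eye UMIs of Gpha2 in the LSC* cells added, and Krt12 in Wing, 1.02 before, to 0.945. Ratios of class shares became 1.11 for Squam, 1.48 for TAC1, 1.68 for TAC2 and 0.720 for Wing, from 1.03, 1.18, 1.30 and 0.638. Without the 10 cells of each library with the most counts of the gene, Cxcl1 turned to 1.85.

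With classes from own clusters the ratio of shares was 0.636 for Basal, 1.37 for Conj, 3.36 for LSC, 1.37 for Squam, 1.64 for TAC1 and 0.573 for Wing, against 0.718, 1.25, 2.36, 1.03, 1.18 and 0.638 in the authors' classes. Each own cluster took the name of its most common class. The cluster named TAC1*, with 1027 dry eye cells, held 456 TAC1* and 440 TAC2* cells of that library. The cluster named Wing*, with 690 dry eye cells, joined 366 Wing*, 204 Squam* and 76 LSC* cells of that library. Both held 0 control cells, and together they held 1717 dry eye cells. In the authors' classes the ratios of shares were 3.78 for TAC1*, 39.5 for Wing* and 11.1 for all starred classes. In own clusters, with 0 control cells, they were 364, 245 and 609 against a floor of 3 control cells, which are not exact lower limits. The ratios of 364 and 245 describe these mixed clusters and are no alternative values for the TAC1* and Wing* shares. The ratio of shares of cycling cells, 1.60, was 1.90 in own clusters, 1.43 among LSC, TAC and Basal cells, 1.39 without starred classes and 1.25 with starred cells not counted as cycling. The ratio of shares of cells with a Mki67 or Top2a UMI, 1.47, was 1.58 without thinning, 1.34 for at least 2 UMIs and 1.27 among LSC, TAC and Basal cells.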

Other observations

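Other fixed lists held single genes that differed while their medians stayed near 0. In the oxidative stress list (median -0.15, 5 of 18 members at least 1.5-fold higher), Gpx2 was 6.01-fold (4.48 to 8.21), or 2.96-fold without starred cells, and Hmox1, heme oxygenase, 2.45-fold (2.14 to 2.82) higher in dry eye, while Sod2 had a ratio of 0.751 and Gclc of 0.822. In the osmotic stress list (median -0.01, 2 of 11 higher), Hspa4l was 1.96-fold (1.80 to 2.13) higher beside Akr1b8, but Nfat5, the transcription factor of the osmotic response, had a ratio of 0.760 (0.737 to 0.785) and the water channel Aqp3 one of 0.779. Of the tight junction and desmosome list (median 0.04, 1 of 19 higher and 1 lower), Cldn1 was 3.21-fold (2.96 to 3.47) and Cldn4 1.38-fold higher, with Dsg1a at 0.615 and Dsc3 at 0.804. Of the apoptosis and p53 list (median 0.07, 2 of 14 higher), Pmaip1 was 4.07-fold and Fas 2.34-fold higher, and Gadd45a stood at 0.756 and Ccng1 at 0.899. Among EGFR ligands and feedback genes (median 0.04, 3 of 13 higher), Areg and Hbegf, ligands of epithelial repair, were 1.72-fold (1.63 to 1.80) and 1.66-fold (1.64 to 1.69) higher, and Btc and Spry1 stood at 0.724 and 0.824.

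Mucin and glycocalyx genes had a median of 0.08 with 0 of 8 past 1.5-fold, from Galnt12 at 0.752 and Muc15 at 0.788 to Muc4 at 1.11; Fut2 had only 22 and 29 UMIs. Notch genes had a median of -0.05 with 0 of 10 past it, from Notch3 at 0.717 and Jag1 at 0.797 to Nrarp at 1.14 and Jag2 at 1.27. Wnt genes had a median of -0.11, with Dkk3 at 0.758 and Fzd7 at 0.804, Axin2 at 1.23 and 0.980 at the control class shares, and Tcf7 4.62-fold higher on 13 and 65 UMIs. Nuclear genes of oxidative phosphorylation had a median of -0.01, from Sdhb at 0.797 and Sdha at 0.825 to Cycs at 1.17 and Ndufa4 at 1.41. Immediate early genes had a median of -0.01, with Fosb at 1.91 and Ier3 at 1.57, and Hspa1a at 0.700 and Hspb1 at 0.843. Summed marker lists had 6910 CPM in control and 7784 in dry eye for limbal epithelium, 7989 and 9579 for basal, 280 and 422 for cycling, 40865 and 36438 for wing and 15043 and 11349 for superficial epithelium. The limbal sum was mostly Krt15, at 4264 and 4033 CPM, which had 15507.5 CPM in Conj and 6285 in LSC cells. Ifitm1 of that list had 8537 CPM in Squam and 1920 in LSC cells. The limbal sum is thus no measure of limbal cells alone.

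Of the tests below, 6 were chosen only after the result was seen: those of a whole-library shift, of fewer upper-layer cells, of fewer resting cells, of a few cells rich in chemokines, of a few cells rich in Tnf and of 1 cell under 2 barcodes. The starred classes came mostly from the dry eye library. Without the 5% of cells with the most UMIs, starred cells were still 10.5% (10.1 to 11) of dry eye and 1.01% of control cells. This could not exclude very deep cells, as doublets would give, because those 5% were fewer than the 10.9% of dry eye cells that were starred. In dry eye each starred class had a higher median of UMIs than its unstarred class, such as LSC* (16145 against 5478.5) and Wing* (17483.5 against 11815). Doublets therefore stay open. A shift of the whole dry eye library, such as free RNA, stays open. The 22 genes that mark starred cells had a median log2 ratio of 0.88 (0.30 to 1.48) between libraries in Basal cells, which carry no asterisk. Between starred and unstarred dry eye cells it was 2.73, but these genes were picked for being higher in those starred cells, which raises that value. A response to dissociation in part of the cells cannot be told apart from the treatment either. The immediate early list had a median log2 ratio, starred over unstarred within dry eye, of 0.17 over the 5 pairs of classes, but 1.27 in LSC*. A response of the epithelium to drying remains a hypothesis.

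Cells of the cycling classes were more frequent in dry eye. After thinning, 11.02% (10.5 to 11.5) of dry eye and 7.51% (7.11 to 7.93) of control cells had a Mki67 or Top2a UMI. Deeper sequencing thus did not account for the higher share of cells with these UMIs, though the background in Squam and Squam* cells was also higher, 1.47% against 0.502%. For the class shares thinning cannot decide, because cells were not classed again after it. Fewer wing, superficial and conjunctival cells did not account for the higher share of the cycling classes. Among LSC, TAC and Basal cells alone the TAC classes made up 53.03% (51.9 to 54.2) of dry eye and 37.1% (36.0 to 38.3) of control cells. Of these upper and conjunctival cells only Wing with Wing* took a smaller share of dry eye cells, 23.4% against 32.4%. Squam with Squam* took 19.4% against 17.5%, and Conj 11.2% against 8.96%. A loss of resting Basal cells alone did not account for the rise of the TAC classes. Among all cells but Basal the TAC classes made up 29.4% (28.7 to 30.2) of dry eye and 20.1% (19.4 to 20.8) of control cells, and TAC1 and TAC2 alone 21.7% (21.0 to 22.4) and 18.9% (18.3 to 19.6). A joint loss of Basal and upper-layer cells stays open beside more dividing cells, because cells per cornea were not counted.

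Counts of Cxcl2, Ccl20 and Tnf were higher in the control library. A few cells carried those of Cxcl2 and Ccl20: 10 control cells held 96.2% of the control counts of these 2 genes, and the 2 deepest of the 12 control Wing* cells held 47.8% of those of Cxcl2. They did not carry those of Tnf, with 622 UMIs in 217 control and 189 in 135 dry eye cells: 10 cells held 27.5% of its control counts, and its ratio of 0.281 (0.238 to 0.331) was 0.318 (0.263 to 0.383) without the 10 cells of each library with the most. Those 2 cells may be 1 cell counted under 2 barcodes, but no value decided this: they differed by a chi-square per degree of freedom of 1.46 over 747 genes, above the bound of 1.2 set for a single cell. Of the other pairs of these cells 3 were as close or nearly so, at 1.0, 1.5 and 2.16, and the next stood at 4.82, so the range of other pairs, which the test was to use, held further possible duplicates; this reading was made after the values were seen. No biological explanation was tested.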
